A study of Equus caballus with 20 samples.

How the data were processed

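Gene expression had been measured by RNA sequencing in oviduct epithelium of Warmblood mares, collected 4 days after ovulation where the ampulla, the wide upper part of the tube, meets the isthmus, the narrow part leading to the uterus. Per the labels, 20 libraries fall into 4 groups of 5 biological replicates. Pregnant and cyclic (not pregnant) mares were each sampled in the oviduct on the side of ovulation (ipsilateral) and in the one on the other side (contralateral). Libraries are named here by group and replicate number: PI for pregnant ipsilateral, PC for pregnant contralateral, CI for cyclic ipsilateral and CC for cyclic contralateral. All 20 columns of the table matched 1 sample each by name.

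Per the labels' protocols, the libraries were made with a stranded total RNA kit after depletion of ribosomal RNA, whereas another label gives polyA RNA as the molecule. Whether RNA without a polyA tail was measured is therefore open. CASAVA 1.8, Illumina's base calling and demultiplexing software, is the tool given in the submitters' processing notes. The aligner, the read counter and its strand setting, the genome build, the annotation and any filter are not given in the sources used here. No coordinates are printed for that reason. Overlapping and antisense genes stay uncertain, as do genes with near-identical copies, such as the MHC class II genes, whose reads the counting could have split between copies.

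The authors deposited TMM-normalized counts per gene, a signal in which the read counts of each library are multiplied by 1 factor that brings libraries to a common scale. In each column the values above 0 were whole multiples of the smallest one, so the whole reads behind them were recovered: 100% of the values came out whole within a tolerance of 0.01 reads. The recovered totals ran from 2795168 reads (PI1) to 10126484 (CI2). A gene with no read in a library could still have had up to 3 reads, which is 1.75 to 7.03 normalized counts depending on the library; such floors, and the exact (Clopper-Pearson) intervals given for shares, cover counting error only. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 17.5 to 149 over the 40 pairs within groups and 4.96 to 203 over the 10 pairs of the same status and number.

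The file lists 26740 features, by symbol or by Ensembl identifier, of which 20350 had reads. The reference gene table at hand pairs no Ensembl identifiers with symbols, so features listed by Ensembl identifier kept it. Features above 1 CPM (counts scaled to library total) in at least 5 libraries were kept, 14692 in all, of which 12430 had a symbol and 2262 an Ensembl identifier.

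Tests were run on log2 of the deposited value plus a pseudocount of 0.5 CPM, equal to 3.03 normalized counts; folds on this scale understate the change of low genes. One limma model (3.58.1, R 4.3.3) with 4 group means was fitted to all 20 libraries, with empirical Bayes moderation (trend and robust), 2-sided tests and Benjamini-Hochberg adjustment at 0.05. It gave 5 comparisons: pregnant against cyclic mares on each side, ipsilateral against contralateral oviduct in each status, and the interaction of pregnancy and side. Log2 differences are given with their standard error (SE) and levels as mean normalized counts with their standard deviation (SD) over the 5 libraries of a group. The design was fixed before the data were examined, and with it 28 gene lists from textbook knowledge, covering immune pathways, epithelial functions and markers of other cell types, and the alternatives not said to be added later. Lists with at least 5 members kept (25 of 28) were tested with camera, limma's competitive gene set test, which compares a list with all other genes. Its preset correlation between genes was 0.01, and its adjusted p with a correlation estimated from the data is printed beside each call. The median log2 difference over members describes a list. In 18 of the 125 list tests the median, the mean and the direction of the test differed in sign, 0 of them called. List scores are the mean log2 value of the members in a library. They were also compared by an exact permutation test over the 252 arrangements of 5 against 5 libraries, whose smallest possible p is 0.00794.

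Genes named in the text are 18 fixed genes, whatever their p, and, since fewer than 5 genes passed in each comparison, the 3 with a symbol and the smallest p of each comparison, said not to pass. PGR and C3 were not found under those symbols, and HPGD lay below the filter. Of the genes that this rule names, 2 are not reported here. All other named genes were chosen after their values were seen, to illustrate the lists or alternatives they belong to.

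The procedure was tested on simulated data for the ipsilateral comparison of pregnant with cyclic mares (14482 genes). Of 100 genes changed 2-fold 57 were recovered, and of 100 changed 4-fold 95, among 165 calls. Of the other calls 3 were genes of a list moved 1.5-fold and 10 were false. Camera called that list of 40 genes (adjusted p = 2.4e-24) and 0 of 20 unmoved lists. All changed genes were drawn from those averaging over 5 CPM, so recovery of genes between the 1 CPM filter and that level was not measured. The simulated genes and libraries were drawn independently of each other. In the real data the correlation estimated for interferon-stimulated genes in that comparison was 0.764. The simulation therefore could not show false list calls that arise from correlated genes.

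The labels give replicate numbers 1 to 5 in every group without saying that a number marks a mare. In pregnant mares the deviations from the group means correlated between the 2 oviducts of the same number (r across genes 0.70, 0.60, 0.53, 0.64 and 0.59 for numbers 1 to 5), each higher than with any other number. The numbers thus pair the pregnant libraries, and blocked values are printed beside that comparison of sides where they change a call.

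Alternatives were other pseudocounts and filters, CPM values without TMM, median-of-ratios scaling, library weights, non-robust moderation, the 2 compared groups alone, replicate blocks, leaving out each library, scores of leukocyte, stromal and multiciliated markers as covariates, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were log2 reads as a covariate, the fit without the 3 libraries in which 1 feature took over 10% of the reads, the exact permutation of list scores, the mean pregnancy difference over both sides, and the count of genes shared by the sides over other splits. For lists the marker covariates, filters, library weights, non-robust moderation and 2-group fits were also added then, and for the overlap of the sides all but pseudocounts, filters and left-out libraries.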

Results

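The transcriptomes of 20 oviduct epithelium libraries were compared, 5 from each combination of pregnancy status and side. Groups are pregnant ipsilateral (PI), pregnant contralateral (PC), cyclic ipsilateral (CI) and cyclic contralateral (CC). Genes of multiciliated cells were among the most abundant transcripts, with DNAH5, a dynein heavy chain of motile cilia, at 23077 ± 3753 and HYDIN, a protein of the ciliary axoneme, at 15283 ± 2875 normalized counts (SD, n = 20). CD74, the invariant chain of MHC class II molecules, stood at 31757 ± 15678 and CLU, the secreted chaperone clusterin, at 15742 ± 5599. OVGP1, the oviduct-specific glycoprotein, was near the counting floor in all groups, with means of 3.02 to 6.66 normalized counts. The feature with the most reads, ENSECAG00000014226, which has no symbol in the file, took 0.310% of the reads in CC5 and 27.8% in PI4 (95% exact interval 27.8 to 27.8). It also exceeded 10% in PI1 (14.4%) and CI3 (15.4%). Mitochondrial transcripts took 1.27% (CC2) to 8.62% (CI3) of the reads.

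The first comparison asked how gene expression beside the ovulating ovary differs when the mare is pregnant. Interferon-stimulated genes, the antiviral effectors and sensors that interferons induce, were higher in the ipsilateral oviduct of pregnant mares in 41 of 45 measured members, with a median log2 difference of 0.76 (camera, adjusted p = 2.7e-17; adjusted p = 0.758 with an estimated correlation). The ubiquitin-like modifier ISG15 averaged 206 ± 168 normalized counts in PI and 38.6 ± 28.5 in CI (SD, n = 5), a log2 difference of 1.82 ± 0.81 (SE). MX1, an antiviral GTPase, differed by 1.41 ± 0.55 and the transcription factor IRF7 by 1.61 ± 0.91, but the chemokine CXCL10 by −0.09 ± 0.81. Per library, the list scores were 8.77, 7.07, 8.96, 8.98 and 6.38 in PI1 to PI5 and 8.20, 6.89, 7.11, 6.62 and 7.11 in CI1 to CI5, and the exact permutation test gave p = 0.183. PI1, PI3 and PI4 scored above every CI library, whereas PI2 and PI5 did not. The median was 1.21 without PI5 and 0.31 without PI1, PI4 and CI3.

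Markers of T and NK cells were also higher, in 17 of 19 members, with a median of 0.69 (adjusted p = 1.1e-06; adjusted p = 0.758 with an estimated correlation). Per library they did not follow the interferon list throughout. PI2 had the highest T and NK score of the PI libraries (5.29), but an interferon score of 7.07, within the CI range. CD3E, a chain of the T cell receptor complex, averaged 34.3 ± 12.2 in PI and 23.1 ± 19.4 in CI, and the pan-leukocyte gene PTPRC 277 ± 87.4 and 225 ± 163 normalized counts (SD, n = 5). MHC class II genes, which present antigen to helper T cells, were higher in 13 of 15 members with a median of 0.41 (adjusted p = 0.0072; adjusted p = 0.758 with an estimated correlation). CD74 differed by 0.59 ± 0.35 and CIITA, their master regulator, by 0.41 ± 0.42. Cytokines and chemokines were higher in 19 of 24 members, with a median of 0.26 (adjusted p = 0.0152; adjusted p = 0.758 with an estimated correlation).

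Multiciliated cell markers were higher in 36 of 40 members by a small amount, a median of 0.20 (adjusted p = 8.0e-06; adjusted p = 0.758 with an estimated correlation). DNAH5 differed by 0.28 ± 0.16, HYDIN by 0.30 ± 0.18 and FOXJ1, the master regulator of motile cilia, by 0.24 ± 0.18. Stromal fibroblast markers were lower in 18 of 19 members, with a median of −0.42 (adjusted p = 6.5e-05; adjusted p = 0.758 with an estimated correlation). The proteoglycan OGN differed by −1.0 ± 0.40 and the collagen chain COL1A2 by −0.42 ± 0.48, while POSTN, a matrix protein of activated fibroblasts, was the exception at 0.41 ± 0.58. Genes of endoplasmic reticulum stress and protein folding were lower in 17 of 22, with a median of −0.18 (adjusted p = 0.0417; adjusted p = 0.816 with an estimated correlation). The chaperone HSPA5 differed by −0.19 ± 0.27.

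Other groups gave no call on this side. Medians were −0.02 for MHC class I (camera adjusted p = 0.631), 0.27 for complement (0.0504) and 0.08 for proliferation (0.415), TOP2A at −0.07 ± 0.60. They were −0.07 for oviduct secretory cell markers (camera adjusted p = 0.498), −0.04 for steroid receptors and response (0.224), 0.08 for antimicrobial and mucosal defence (0.733), −0.08 for pattern recognition and NF-kappaB signalling (0.696), −0.12 for extracellular matrix remodelling (0.224), and 0.00 for immediate-early and heat shock genes (0.793). The prostaglandin list had a median of −0.09 against a mean of 0.09 (adjusted p = 0.922). Medians of other cell types were −0.06 for smooth muscle, whose mean was 0.07 (adjusted p = 0.733), −0.16 for B and plasma cells (0.733), −0.03 for monocytes, macrophages and dendritic cells (0.697), and 0.11 for mesothelial and ovarian cells (0.415). The estrogen receptor ESR1 averaged 1796 ± 415 in PI and 2447 ± 179 normalized counts in CI, a log2 difference of −0.48 ± 0.24. The prostaglandin E2 receptors PTGER2 and PTGER4 differed by 0.19 ± 0.19 and 0.46 ± 0.32. The prostaglandin synthases PTGS2 and PTGES by 0.34 ± 0.46 and −0.14 ± 0.44. The smooth muscle myosin MYH11 differed by −0.34 ± 0.55 and the collagen chain COL1A1 by −0.05 ± 0.67. Neutrophil and mast cell (2 genes kept), erythrocyte (3) and uterine gland (3) lists were too short to test, with mean scores of 4.6 ± 0.71, 5.39 ± 0.27 and 6.99 ± 0.44 in PI and 4.81 ± 0.81, 4.94 ± 0.30 and 7.33 ± 0.59 in CI (SD, n = 5).

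No single gene passed: limma called 0 of 14692 genes, and 514 had an unadjusted p under 0.05. While 0.05 of all genes is 735, other splits of the PI and CI libraries into equal groups gave a median of 380. On the recovered reads, edgeR called 0 (494 unadjusted) and DESeq2 0 (560 unadjusted). The 3 smallest p values belonged to genes lower in pregnant mares that did not pass (adjusted p = 0.451 each). The metalloprotease ADAMTS18 had only 0 to 10 reads in the PI libraries, at or near the floor, so the size of its difference depends on the pseudocount. It averaged 3.61 ± 3.63 in PI and 29.8 ± 15.7 in CI, a log2 difference of −2.40 ± 0.49. The peptidase NLN averaged 86.6 ± 9.49 and 140 ± 13.6 (−0.67 ± 0.14), and SEMA6A, a guidance molecule, 204 ± 41.2 and 341 ± 39.5 normalized counts (−0.74 ± 0.15; SD and SE, n = 5). Adjusted over the list alone, 1 gene passed over all lists: the matrix metalloproteinase MMP7, at 11.6 ± 5.81 in PI and 54.4 ± 24.8 in CI (adjusted p = 0.00435 within the extracellular matrix list, limma). The call on MHC class II genes ended without PI3, PI4, CI3 or CI5 (medians 0.20 to 0.25), and the median was 0.69 without PI5 and 0.66 without CI1. With PI1, PI4 and CI3 left out the direction of that test turned (adjusted p = 0.978), and the calls on stromal markers (median −0.02) and cytokines (0.05) ended. The stromal median was −0.22 without PI1. The T and NK median was 0.39 without those 3 libraries and 1.06 without CI1. The cytokine call ended without PI3, PI4, CI3, CI4 or CI5 (0.16 to 0.28), with 0.12 without PI1. The multiciliated median was 0.10 without CI1, and the endoplasmic reticulum call ended without PI1, PI3, PI5, CI1, CI2 or CI4 (−0.10 to −0.18).

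Covariates also moved these lists ipsilaterally. With the leukocyte marker score the calls on MHC class II (median 0.0903, adjusted p = 0.292) and cytokines (0.0866, adjusted p = 0.246) ended. With log2 reads the endoplasmic reticulum call ended (−0.00367, adjusted p = 0.915), and the medians were −0.18 for stromal and 0.11 for multiciliated markers. The endoplasmic reticulum call also ended with the smooth muscle and stromal score (−0.08) and the multiciliated score (−0.06). Stromal markers were at −0.25 with the multiciliated score, and multiciliated markers at 0.13 with the smooth muscle and stromal score. Scores made of a list's own members took stromal markers to −0.12 and multiciliated ones to 0.02, ending both calls, and T and NK markers to 0.39. With a pseudocount of 2 CPM T and NK markers were at 0.45.

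**Figure D1:**
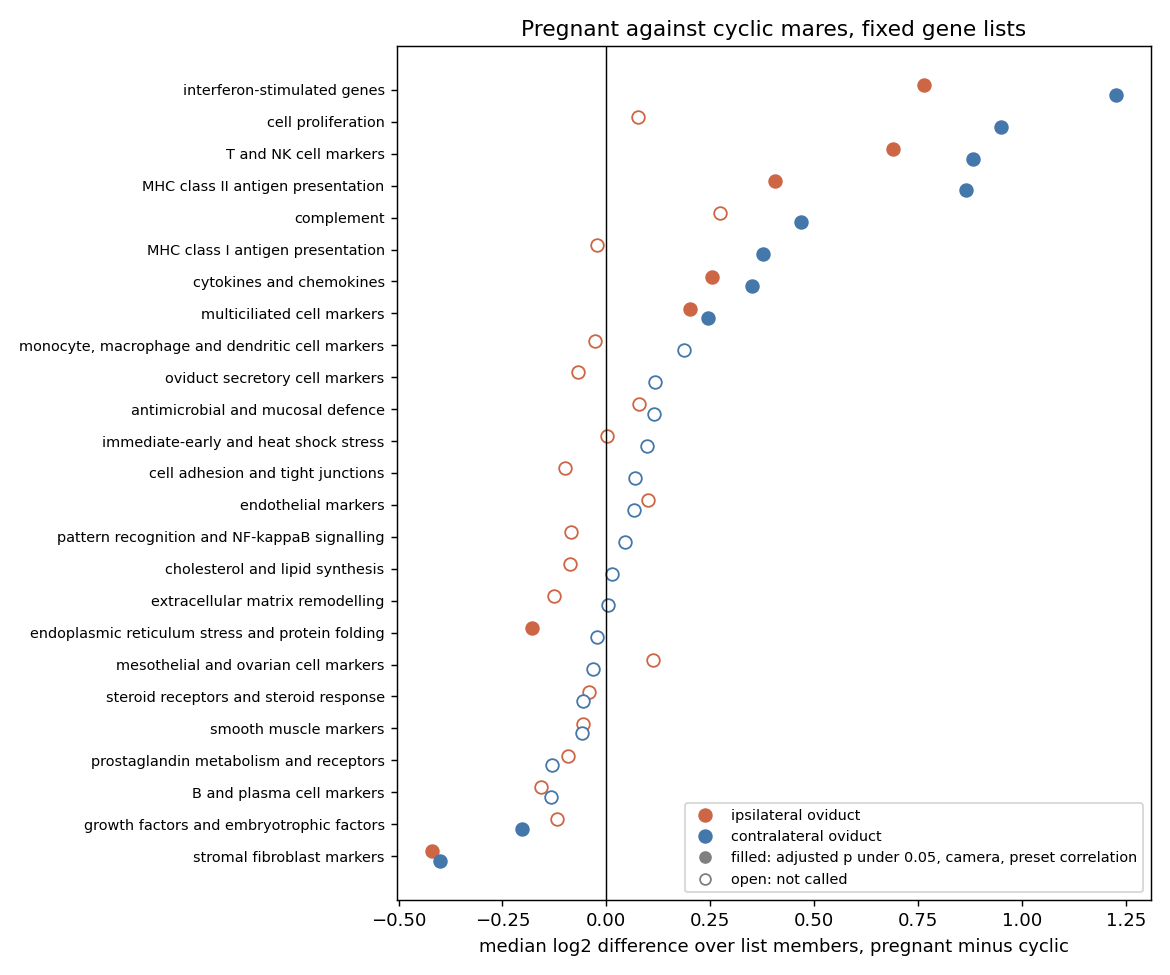
Median log2 difference between pregnant and cyclic mares over the members of each gene list (x axis, log2 of normalized count plus pseudocount) for the 25 tested lists (y axis), in the ipsilateral (orange) and contralateral (blue) oviduct; filled points have an adjusted p under 0.05 by camera with the preset correlation, open points do not. The interferon-stimulated list lies at 0.76 and 1.23, and stromal fibroblast markers lie at −0.42 and −0.40.

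On the side away from ovulation, the same question gave a wider set of lists. All 45 interferon-stimulated genes were higher in pregnant mares, with a median of 1.23 (camera, adjusted p = 3.6e-33; adjusted p = 0.269 with an estimated correlation; exact permutation p = 0.0714). ISG15 averaged 225 ± 187 in PC and 29.0 ± 12.1 normalized counts in CC (SD, n = 5), a log2 difference of 2.21 ± 0.81 (SE). MX1 differed by 1.69 ± 0.55, IRF7 by 2.23 ± 0.91 and CXCL10, a chemokine that draws activated T cells, by 1.96 ± 0.81. List scores were 8.73, 6.88, 9.12, 9.29 and 7.09 in PC1 to PC5 and 6.51, 6.72, 7.23, 6.59 and 7.48 in CC1 to CC5. PC1, PC3 and PC4 scored above every CC library, and PC2 and PC5 lay within the CC range. Numbers 1, 3 and 4 were thus high in both oviducts, so the 2 sides do not support the pattern separately. MHC class II genes were higher in 14 of 15 members, with a median of 0.87 (adjusted p = 2.0e-08; adjusted p = 0.269 with an estimated correlation). Their exact permutation p was 0.00794, the smallest the design allows, and 0.198 after adjustment over 25 lists. CD74 averaged 40760 ± 15065 in PC and 20800 ± 3433 in CC. Components of MHC class I presentation were higher in 14 of 15, with a median of 0.38 (adjusted p = 2.5e-04; adjusted p = 0.614 with an estimated correlation). B2M, the light chain of class I molecules, differed by 1.14 ± 0.56 and the peptide transporter TAP1 by 1.5 ± 0.58. Complement genes were higher in 14 of 15, with a median of 0.47 (adjusted p = 2.0e-04; adjusted p = 0.303 with an estimated correlation), CLU among them at 0.44 ± 0.31. Cytokines were higher in 19 of 24, with a median of 0.35 (adjusted p = 0.0412; adjusted p = 0.623 with an estimated correlation).

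T and NK cell markers were higher beside these groups in 17 of 19 members, with a median of 0.88 (adjusted p = 5.6e-11; adjusted p = 0.269 with an estimated correlation; exact permutation p = 0.0238, or 0.298 adjusted). PTPRC averaged 336 ± 207 in PC and 182 ± 49.3 in CC, and GZMA, a protease of cytotoxic lymphocytes, 39.8 ± 39.2 and 16.4 ± 7.14 normalized counts (SD, n = 5). Cell proliferation genes were higher in all 28 members, with a median of 0.95 (adjusted p = 2.0e-14; adjusted p = 0.303 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, differed by 1.24 ± 0.60 and the mitotic kinase CDK1 by 1.07 ± 0.52. Multiciliated cell markers were higher in 39 of 40, with a median of 0.24 (adjusted p = 1.2e-08; adjusted p = 0.269 with an estimated correlation), FOXJ1 among them at 0.32 ± 0.18. Stromal fibroblast markers were lower in 17 of 19, with a median of −0.40 (adjusted p = 0.00136; adjusted p = 0.623 with an estimated correlation), COL1A2 at −0.68 ± 0.48 and again with POSTN as an exception at 0.76 ± 0.58. Growth factors and embryotrophic factors were lower in 18 of 28, with a median of −0.20 (adjusted p = 0.00629; adjusted p = 0.315 with an estimated correlation). ESR1 differed by −0.40 ± 0.24, PTGER2 by 0.45 ± 0.19, PTGER4 by 0.56 ± 0.32, PTGES by −0.89 ± 0.44 and PTGS2 by 0.27 ± 0.46. PTGES had 1 to 12 reads in the PC libraries, near the floor in some.

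By limma 0 of 14692 genes passed, with 669 at an unadjusted p under 0.05. While 0.05 of all genes is 735, other splits of the PC and CC libraries into equal groups gave a median of 519. On the recovered reads edgeR called 0 (838 unadjusted) and DESeq2 6 (950 unadjusted): ANPEP, LRCH2, NLN, NTNG1 and SLC15A2, lower in pregnant mares, and CCDC96, higher. The smallest p values by limma were those of NLN at 90.3 ± 16.5 in PC and 153 ± 12.8 in CC (log2 difference −0.76 ± 0.14, adjusted p = 0.218), the aminopeptidase ANPEP at 367 ± 65.7 and 739 ± 154 (−1.0 ± 0.19, adjusted p = 0.218) and NTNG1 at 32.0 ± 9.81 and 88.2 ± 20.2 normalized counts (−1.40 ± 0.28, adjusted p = 0.321), none of which passed (SD and SE, n = 5). ADAMTS18 and MMP7 differed by −1.86 ± 0.49 and −1.62 ± 0.42, and MMP7 was again the 1 gene to pass adjusted over the list alone (adjusted p = 0.0257, limma). ADAMTS18 had 1 to 23 reads in the PC libraries, near the floor in some. With library weights 6 genes passed, and with CPM (the values scaled to total reads) without TMM 1, ANPEP. Without PC4 the medians were 0.56 for proliferation, 0.49 for MHC class II, 0.56 for T and NK cells and 0.28 for complement, and the MHC class I call ended (0.19), as it did without CC4 (0.20). The stromal call ended without CC2 (−0.19) or CC3 (−0.10), with medians of −0.75 without CC5 and −0.62 without PC3, and the proliferation median was 0.62 without CC1. The cytokine call ended without PC1, PC3, PC4, CI3, CC2 or CC4 (0.17 to 0.35), and that on growth factors without PC1, CC1, CC2 or CC3 (−0.12 to −0.17), with −0.39 without CC5.

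Contralaterally, the leukocyte marker score as a covariate ended the calls on MHC class I (median −0.0132, adjusted p = 0.883) and complement (0.14, adjusted p = 0.124) and turned the direction of the cytokine test (adjusted p = 0.979). It took interferon-stimulated genes to 0.72, MHC class II to 0.23, proliferation to 0.48 and T and NK markers, which it contains, to 0.32. With log2 reads the calls on MHC class I (0.18, adjusted p = 0.0706) and cytokines (0.25, adjusted p = 0.163) ended, with complement at 0.31 and stromal markers at −0.66. With the multiciliated score the calls on stromal markers (−0.03, adjusted p = 0.762), growth factors (−0.12), cytokines (0.21) and multiciliated markers themselves (0.01) ended, and MHC class I was at 0.58. With the smooth muscle and stromal score those on stromal markers (−0.08), growth factors (−0.11) and cytokines (0.30) ended. Library weights ended the cytokine call (0.22) and gave 0.23 for MHC class I, 0.57 for MHC class II, −0.75 for stromal markers and −0.34 for growth factors. The filter at 5 CPM ended the calls on cytokines (0.21) and growth factors (−0.0849), and a pseudocount of 2 CPM gave 0.195 for cytokines. Without PI1, PI4 and CI3 the cytokine call ended (0.35, adjusted p = 0.0639).

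**Figure D2:**
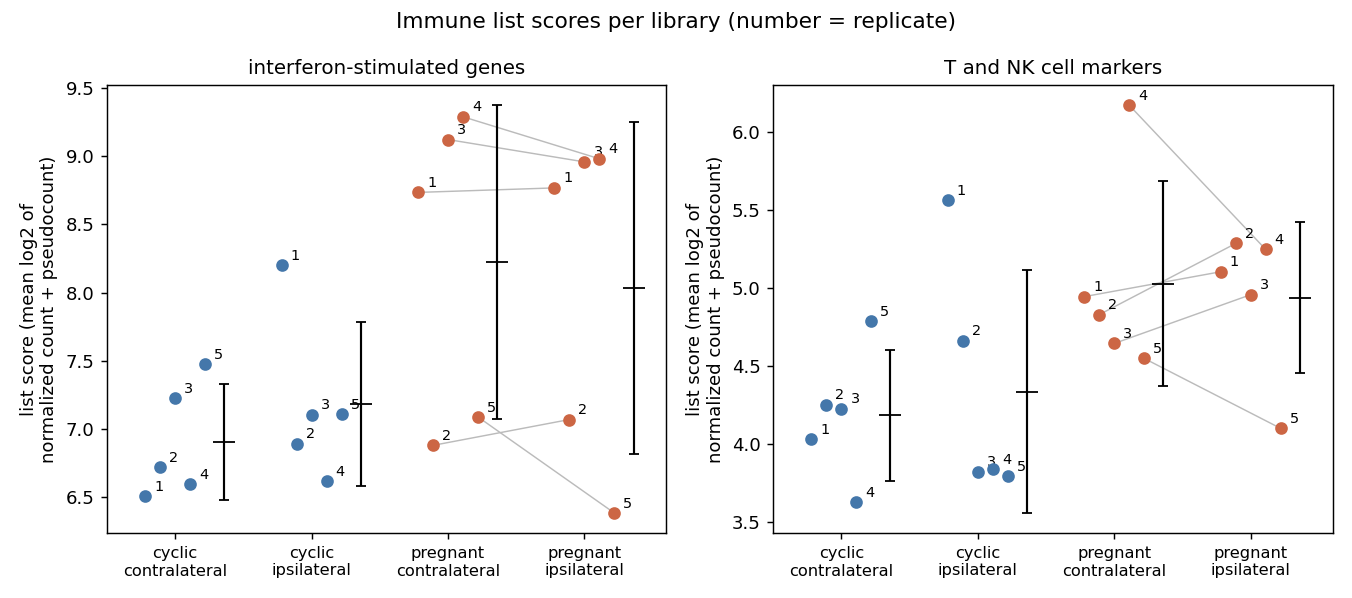
List score per library (y axis, mean log2 of normalized count plus pseudocount) for interferon-stimulated genes (left) and T and NK cell markers (right) in the 4 groups (x axis), with the replicate number beside each point, group mean ± SD as bars (n = 5), and lines between pregnant libraries of the same number. Interferon scores in pregnant mares ran from 6.38 (PI5) to 9.29 (PC4), and in cyclic mares from 6.51 (CC1) to 8.20 (CI1).

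Across the 14692 genes, the pregnancy differences of the 2 sides correlated (Pearson r = 0.594, Spearman rho = 0.484, genes not being independent replicates), and 65.4% of genes had the same sign. The jackknife SE of r was 0.322, and over 38 alternatives r ran from 0.297, without PI1, PI4 and CI3, to 0.680. At an unadjusted p under 0.05, 80 genes were higher and 119 lower on both sides, 199 in all. Other splits that keep the libraries of a status and number together gave a median of 79 such genes and up to 952. Counting the real grouping, 22 of 100 splits had 199 or more.

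The comparison of sides asked whether the oviduct beside the ovulating ovary differs from the other one. In pregnant mares it showed small differences, all 6 called lists being lower on the ipsilateral side. Genes of cell adhesion and tight junctions were lower in all 24 members, with a median of −0.22 (camera, adjusted p = 0.00137; adjusted p = 0.864 with an estimated correlation). Genes of endoplasmic reticulum stress and protein folding were lower in 18 of 22, with a median of −0.19 (adjusted p = 0.00137), HSPA5 at −0.37 ± 0.27 and the secreted factor MANF at −0.44 ± 0.30. Proliferation genes were lower in 24 of 28 (median −0.37, adjusted p = 0.00483), MHC class I in 14 of 15 (−0.31, adjusted p = 0.00483), cholesterol and lipid synthesis in 22 of 26 (−0.17, adjusted p = 0.0110) and MHC class II in 15 of 15 (−0.32, adjusted p = 0.0479). With an estimated correlation each of these 5 also had adjusted p = 0.864. Interferon-stimulated genes had a median of −0.17 (adjusted p = 0.172), complement −0.24 (adjusted p = 0.158) and extracellular matrix remodelling −0.20 (adjusted p = 0.0889). With the replicate number as a block these 3 were called as well (adjusted p = 0.00903, 0.0388 and 0.0480). With an estimated correlation, and no block, interferon-stimulated genes had adjusted p = 0.952, complement adjusted p = 0.864 and extracellular matrix remodelling adjusted p = 0.864.

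Limma called 0 genes between the sides of pregnant mares (112 at an unadjusted p under 0.05), edgeR 0 (77 unadjusted) and DESeq2 0 (83 unadjusted). Other splits of the PI and PC libraries gave limma a median of 342 unadjusted genes, and 0.05 of all genes is 735. The real grouping parts every pair of libraries and most of those splits do not, so 342 is not a like reference for it. The limma, edgeR and DESeq2 fits, and the single-gene values below, leave the pairs of libraries out of account. With the replicate number as a fixed or random block limma still called 0 genes, with 464 and 455 unadjusted (lowest adjusted p = 0.822 and 0.444). The smallest p values were those of FOPNL, at 61.6 ± 10.1 in PI and 36.9 ± 5.77 in PC (log2 difference 0.69 ± 0.16), DLG2 at 46.7 ± 9.32 and 30 ± 6.17 (0.59 ± 0.21) and the keratin KRT39 at 13.9 ± 4.54 and 5.89 ± 1.51 normalized counts (0.90 ± 0.30), which did not pass (limma, adjusted p = 0.999 each; SD and SE, n = 5). Without PC4 the direction of the proliferation test turned (median −0.01) and the calls on MHC class I (−0.09), MHC class II (−0.02) and cholesterol synthesis (−0.07) ended. Without PI5 the same 4 calls ended (−0.08, −0.01, −0.05 and −0.15). The proliferation call also ended without PI2 (−0.19) or PC3 (−0.32), and the MHC class I call without PC3 (−0.21). The MHC class II call also ended without PI2 (−0.18), PC3 (−0.28), CI4, CC1, CC2, CC4 or CC5 (−0.32 each). Proliferation reached −0.65 without PI4 and −0.62 without PC5, endoplasmic reticulum genes −0.30 without PC1, MHC class II −0.48 without PI4, and adhesion −0.13 without PI1. With log2 reads as a covariate all 6 calls ended (adhesion −0.04, endoplasmic reticulum −0.01, proliferation −0.15, MHC class I −0.07, cholesterol −0.02 and MHC class II −0.10). Without PI1, PI4 and CI3 the adhesion call ended (−0.14, adjusted p = 0.0534), with −0.66 for proliferation and −0.55 for MHC class II. Library weights ended the calls on proliferation (−0.195, adjusted p = 0.351) and MHC class II (−0.21, adjusted p = 0.265). The MHC class II call also ended with the leukocyte score (−0.185), the smooth muscle and stromal score (−0.31), a pseudocount of 0.1 CPM (−0.34), the filter at 5 CPM (−0.33) and CPM without TMM (−0.38).

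In cyclic mares, proliferation genes were higher on the ipsilateral side in 27 of 28 members, with a median of 0.53 (camera, adjusted p = 2.6e-08; adjusted p = 0.486 with an estimated correlation), TOP2A at 0.72 ± 0.60. Endothelial markers were lower in 14 of 14, with a median of −0.34 (adjusted p = 4.0e-05; adjusted p = 0.429 with an estimated correlation). PECAM1, a junction protein of endothelial cells, averaged 22.8 ± 12.6 in CI and 48.3 ± 28.3 normalized counts in CC (SD, n = 5). Interferon-stimulated genes were higher in 42 of 45 (median 0.27, adjusted p = 0.00163; adjusted p = 0.881 with an estimated correlation), and growth factors were lower in 20 of 28 (median −0.09, adjusted p = 0.00881; adjusted p = 0.429 with an estimated correlation). Limma called 0 genes (42 unadjusted), edgeR 0 (50 unadjusted) and DESeq2 0 (55 unadjusted). Other splits of the CI and CC libraries gave limma a median of 452 unadjusted genes, and 0.05 of all genes is 735. JPH1 (0.54 ± 0.18), the signalling ligand WNT2B (−0.55 ± 0.19) and the receptor OPRL1 (−0.47 ± 0.17) had the smallest p values and did not pass (adjusted p = 1.00 each). The proliferation call ended without CC1 (0.16), and the median was 0.35 without CI2. The endothelial median was −0.20 without CI1 and −0.15 without CC3. The interferon call ended without CI1 (0.05), CC1 (0.16), CC2 (0.21) or CC4 (0.18). The growth factor call ended without CI2 (−0.07), CI4 (−0.13), CC1 (−0.07), CC2 (−0.04) or CC3 (−0.01), with medians of −0.14 without CC4 and −0.22 without CC5. Library weights and the leukocyte score each ended the interferon call (0.09 and 0.13), and log2 reads the growth factor call (−0.13). Growth factors were at −0.21 with library weights, −0.14 with CPM without TMM and −0.03 with the filter at 5 CPM, and endothelial markers at −0.52 with library weights and −0.19 with a pseudocount of 2 CPM.

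**Figure D3:**
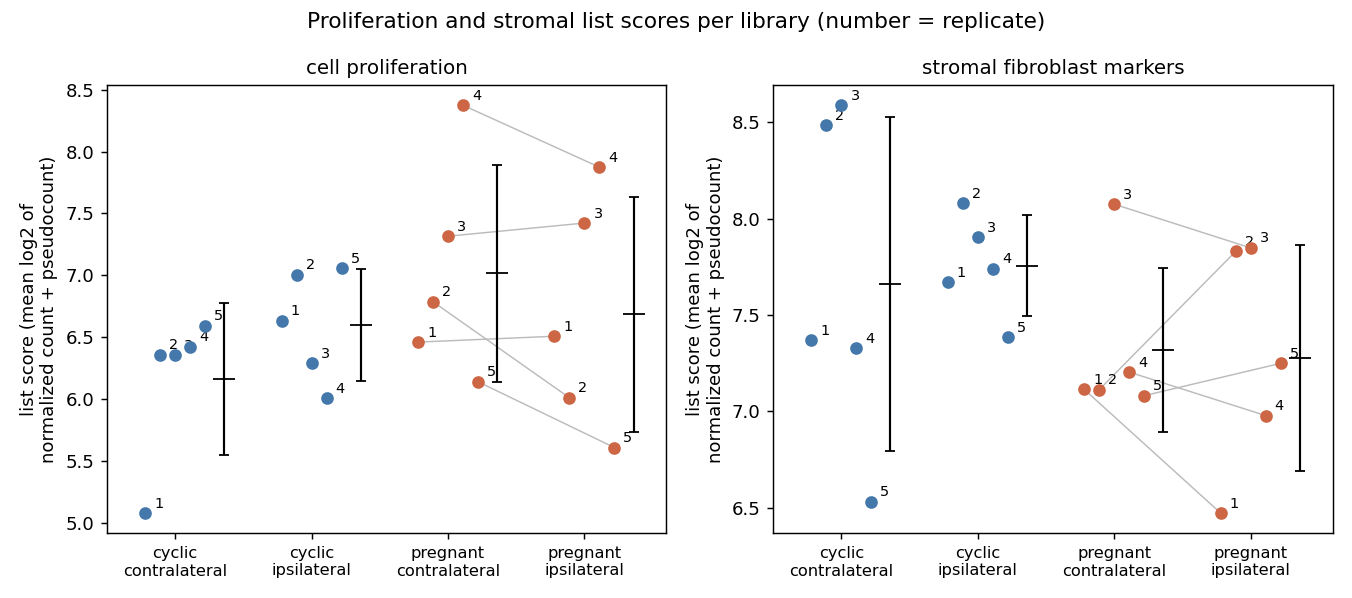
List score per library (y axis, mean log2 of normalized count plus pseudocount) for cell proliferation (left) and stromal fibroblast markers (right) in the 4 groups (x axis), with replicate numbers, group mean ± SD as bars (n = 5), and lines between pregnant libraries of the same number. For proliferation PC4 lies highest at 8.37 and CC1 lowest at 5.08.

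The interaction asked whether the pregnancy difference depended on the side. It was lower on the ipsilateral side than on the contralateral side for proliferation genes in 28 of 28 members, with a median of −0.89 (camera, adjusted p = 1.3e-11), interferon-stimulated genes in 43 of 45 (−0.39, adjusted p = 4.6e-04), MHC class I in 15 of 15 (−0.34, adjusted p = 0.00492) and MHC class II in 15 of 15 (−0.38, adjusted p = 0.0146). It was higher for growth factors in 17 of 28 (0.15, adjusted p = 0.0148). All 5 lists had adjusted p = 0.862 with an estimated correlation. By limma 0 genes passed (47 unadjusted), as by edgeR (39 unadjusted) and DESeq2 (49 unadjusted). Other splits of the libraries gave limma a median of 74 unadjusted genes. These fits, and the single-gene values below, leave any pairs of libraries out of account. With the replicate number as a fixed or random block limma still called 0 genes, with 267 and 225 unadjusted. The phospholipase PLCXD3 (1.63 ± 0.52) and TATDN3 (−0.74 ± 0.26) had among the smallest p values and did not pass (adjusted p = 1.00 each). PLCXD3 had group means of 2.32 to 9.57 normalized counts, at or near the floor in some libraries. The proliferation median was −0.53 without PI5, −0.47 without PC4 and −0.54 without CC1. Without PI5 the interferon test turned (−7.4e-05), and its call ended without PI2, PC1, PC3, PC4 or CI1 (−0.13 to −0.22), while the median was −0.64 to −0.79 without PI1, PI3, PI4, PC2 or PC5. The MHC class I call ended without PI5, PC3, PC4, CI1 or CC4 (−0.13 to −0.26). The MHC class II call ended without PI2, PI5, PC4, CI1, CC1 or CC4 (−0.03 to −0.36), with −0.59 without CI5, and the growth factor call ended without PI2, PI5, PC1, PC4, CC1, CC2 or CC3 (−0.04 to 0.16). The growth factor median was 0.08 to 0.09 without PC2, CI2, CI4 or CI5 and 0.25 without CC5. With log2 reads as a covariate the calls on MHC class I and II ended (0.0256 and 0.04), and proliferation was at −0.52. Library weights ended the calls on interferon-stimulated genes (−0.08), MHC class I (−0.16) and MHC class II (−0.15), as did the leukocyte score (−0.16, −0.17 and −0.14). Without PI1, PI4 and CI3 these lists were at −1.04, −0.56 and −0.79. The growth factor call ended without a filter (0.15), with the filter at 5 CPM (−0.0298) and with the multiciliated score (0.12). Its median was 0.0819 and 0.095 with pseudocounts of 0.1 and 2 CPM and 0.26 with library weights.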

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

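Chosen only after the results were seen were the tests on other splits for the gene counts, the test of a smaller share of non-epithelial cells, the depth covariate, the marker covariates for lists, and the fit without PI1, PI4 and CI3.

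The first pattern is the higher interferon-stimulated list in pregnant mares. With log2 reads as a covariate its median was 0.77 ipsilaterally and 1.22 contralaterally, 101% and 99.2% of the values without it, which argues against library depth as the cause. With a leukocyte marker score as a covariate it was 0.51 and 0.72 (66.8% and 58.4%), still above 0.5 of its size but by less than the spread over members (0.14 and 0.11), so that leukocytes in the samples and a response of the epithelium cannot be told apart. Counting the real grouping, camera p values as small came from 16 of 100 splits of the libraries ipsilaterally (smallest of the others 6.4e-62, real 1.1e-18). Contralaterally they came from 5 of 100 (smallest of the others 8.9e-48, real 1.5e-34), which lies on the 5% line set for chance. Chance in the choice of mares therefore stays open. A response to pregnancy, which the design names, also stays open and needs more mares.

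The second pattern is lower stromal and higher multiciliated markers in pregnant mares. A smaller share of non-epithelial cells would lower the markers of every other cell type. Smooth muscle medians were −0.06 on both sides, and endothelial medians 0.10 ipsilaterally and 0.07 contralaterally. T and NK markers lay above stromal ones by 1.11 ipsilaterally (spread over members 0.25) and 1.28 contralaterally (0.26). That spread does not measure differences between mares. Exact permutation of the ipsilateral list scores gave p = 0.183 for T and NK and p = 0.135 for stromal markers. Contralaterally exact permutation gave p = 0.0238 for T and NK markers before adjustment. Its lowest adjusted p over all lists was 0.198, for MHC class II. The gap between T and NK and stromal markers therefore cannot decide against a smaller share. Counting the real grouping, camera p values as small for the stromal list came from 12 of 100 splits ipsilaterally (smallest of the others 3.5e-12, real 1.0e-05). Contralaterally they came from 39 (smallest of the others 2.9e-20, real 4.4e-04). For the multiciliated list they came from 11 (smallest 2.3e-11, real 9.6e-07) and 5 of 100 (smallest 6.1e-14, real 1.9e-09), counted in the same way. Chance stays open for both lists, though 5 of 100 lies on the 5% line set for it. A loss of fibroblasts alone, at sampling or with pregnancy, also stays open and was not tested. With log2 reads as a covariate stromal and multiciliated medians were −0.18 and 0.11 ipsilaterally (−0.42 and 0.20 without it) and −0.66 and 0.28 contralaterally (−0.40 and 0.24 without it), so that depth stays open for part of the ipsilateral differences.

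The third pattern is the higher proliferation list in the contralateral oviduct of pregnant mares. With log2 reads as a covariate its median was 0.86, 90.1% of the value without it, which argues against depth. Without PC4 it was 0.56 (camera, adjusted p = 3.2e-07), 58.8% of its size and within the spread (0.09) of 0.5 of it. The list score was 8.37 in PC4 and 6.14 to 7.32 in the other PC libraries. CC1 stood apart in the opposite direction, at 5.08 against 6.36 to 6.59 in the other CC libraries. PC4 and CC1 were not left out together, so that a pattern owed mostly to them and one shared by the groups cannot be told apart. Counting the real grouping, camera p values as small came from 9 of 100 splits (smallest of the others 6.8e-22, real 1.6e-15), and chance stays open. With the leukocyte score as a covariate the median was 0.48 (adjusted p = 9.5e-05), and PC4 also stood apart in T and NK markers, so dividing leukocytes stay open beside an effect of pregnancy on cell division in that oviduct.

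Other splits of the libraries often gave as many called lists as the real grouping, which the numbers of splits below include. At least as many lists were called in 44 of 100 splits for pregnancy ipsilaterally (7 real, 14 at most), 27 contralaterally (10, 15), 61 for side in pregnant mares (6, 14), 72 for side in cyclic mares (4, 14) and 66 for the interaction (5, 15). Splits that part all 5 pairs of pregnant libraries numbered 16, of which 7 called at least 6 lists. For genes the real count of 0 fixes the outcome at 100 of 100 splits in every comparison, so that test decides nothing. The highest counts of other splits were 2, 1959, 48, 2608 and 0 genes. The splits with 1959 genes (PC1, PC3, PC5, CC4 and CC5 against the rest) and 2608 genes (CI1, CI3, CI5, CC4 and CC5) part the libraries along the leading principal component, so they reflect structure among the samples.

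For normally distributed values, 16.8 of 336 groups of values would hold a single library far from the other 4 of its group. Gene counts were not put on a log scale and members of a list move together, so that number is a poor guide here. Such single libraries were found in 32 groups of values. Among list scores these were T and NK markers in PI5 (4.10, others 4.96 to 5.29) and PC4 (6.17, 4.55 to 4.95), stromal markers in PC3 (8.07, 7.08 to 7.20), pattern recognition in CI1 (6.78, 6.24 to 6.37), extracellular matrix in CI2 (7.31, 6.79 to 6.94), smooth muscle in CI3 (6.05, 6.40 to 6.52) and CC2 (6.93, 6.36 to 6.52), and proliferation in CC1 (5.08, 6.36 to 6.59). PC4 also stood apart for TOP2A (1728 normalized counts), CD3E (92.4), PTPRC (704) and sequencing depth (10.02 megareads, others 5.52 to 6.51). CI1 did for B2M (18019), CD74 (58488), IFIT1 (297), CXCL10 (275), IRF7 (499), TAP1 (611) and PSMB9 (209). PC3 did for COL1A1 (639), COL1A2 (1315), MYH11 (1380) and SEMA6A (311), and PI3 for COL1A1 (1450) and SEMA6A (277). Others were ESR1 in PI1 (1068), CD3E in PI2 (55.4), MYH11 in CI4 (567), ADAMTS18 (57.6) and mitochondrial reads (8.62%) in CI3, OVGP1 in CC4 (11.7) and PLCXD3 in CC5 (11.5).

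The pregnancy difference itself differed between the sides, by the interaction test, for 5 lists: interferon-stimulated genes (median −0.39), MHC class I (−0.34), MHC class II (−0.38), proliferation (−0.89) and growth factors (0.15). These were called by camera with the preset correlation alone (adjusted p = 0.862 with an estimated correlation).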

How the results depend on the processing

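Chosen only after the results were seen were the fit without PI1, PI4 and CI3, the log2 reads covariate and the exact permutation of list scores, which was not run for the interaction, and for lists also the marker covariates and library weights. Counts of called genes stayed at 0 under all alternatives except for pregnancy contralaterally, where 34 of 38 gave 0; CPM without TMM gave 1 gene, library weights 6, DESeq2 6 and the log2 reads covariate 1 (FOLH1). No list was called (0 in all comparisons) with an estimated correlation or by exact permutation. The interferon medians of 0.76 and 1.23 then had adjusted p = 0.758 and 0.269 with the estimated correlation, and the score differences of 0.85 and 1.32 exact adjusted p = 0.645 and 0.476. The exact test could hardly call a list. For pregnancy contralaterally the smallest p it allows, 0.00794, was reached and became 0.198 after adjustment. Between the sides of pregnant mares it also left the pairs out of account.

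Other counts of called lists moved as follows: pregnancy contralaterally to 6 with the multiciliated covariate; side in pregnant mares to 11 without PI1, PI4 and CI3 and 3 with log2 reads; the interaction to 2 with library weights, 2 with the leukocyte covariate and 9 without PI1, PI4 and CI3. Leaving out each library gave 4 to 9 lists for pregnancy ipsilaterally, 7 to 10 contralaterally, 3 to 10 for side in pregnant and 1 to 11 in cyclic mares, and 1 to 8 for the interaction.

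The direction of the camera test turned, with these medians, for stromal markers between sides (−0.48 in cyclic mares with library weights; 0.24 without PI1, PI4 and CI3 and 0.22 with log2 reads in pregnant mares). With the leukocyte covariate it did contralaterally for macrophage markers (−0.29) and for cytokines, whose median stayed above 0 (0.0289, adjusted p = 0.979). Without PI1, PI4 and CI3 it did ipsilaterally for proliferation (−0.34) and for MHC class II, whose median stayed above 0 (0.0341, adjusted p = 0.978), and with log2 reads for adhesion in the interaction (0.13). Over left-out single libraries the medians ran from −0.52 to 0.22 for interferon genes, −0.22 to 0.24 for T and NK markers and −0.65 to −0.0137 for proliferation between sides of pregnant mares, −0.27 to 0.36 for stromal markers between sides of cyclic mares, and −0.79 to −7.4e-05 for interferon genes in the interaction. The cause was not tested.

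In cyclic mares the data did not settle whether a number marks a mare: CI correlated with CC of the same number at r 0.29, 0.68, 0.02, −0.04 and 0.62, and numbers 1, 2 and 5 but not 3 and 4 were best with their own. A block on the number, fixed or random, called 0 genes throughout. The fixed block called 6, 10, 9, 6 and 6 lists in the 5 comparisons. It ended the call on endoplasmic reticulum genes for pregnancy ipsilaterally (adjusted p = 0.0695), added prostaglandin (0.0487) and smooth muscle lists (0.0361) between sides of cyclic mares and complement in the interaction (0.0399), and apart from the 3 lists given for the sides of pregnant mares changed no other call. With an estimated correlation, and no block, the prostaglandin list had adjusted p = 0.429, smooth muscle adjusted p = 0.431 and complement adjusted p = 0.862. Values of single genes and lists stayed on their side of the threshold in 12904 cases, were called anew in 142 and lost a call in 187. Of 8853 values of named genes 475 had the other sign, for genes without a call. Genes of few reads are limited by depth, 3 reads being up to 7.03 normalized counts.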

Other observations

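Chosen only after the results were seen were the tests of the mean pregnancy difference over both oviducts, of the spread among mares and of the leading component.

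The leading principal component of the libraries held 31.3% of the variance. Across the 20 libraries it went with the scores of endoplasmic reticulum stress and folding (r = 0.97), adhesion and tight junctions (r = 0.95) and cholesterol synthesis (r = 0.90), 3 of the lists called between the sides of pregnant mares. A first hypothesis was that it follows library depth. Over the 10 means per status and number, Spearman rho with log2 reads was 0.867 (permutation p = 0.00214, 0.00428 adjusted over 4 relations) and Pearson r 0.912 (p = 2.0e-04, 8.0e-04 adjusted), or 0.761 without the 2 farthest means. This is consistent with depth, or with something that goes with it, such as RNA yield, which the labels do not give. For the mitochondrial share rho was −0.612 (permutation p = 0.0657, 0.0876 adjusted) and r −0.544 (p = 0.107), or −0.750 without the 2 farthest means, so an effect of it cannot be told apart from none.

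A second hypothesis was that the pregnancy differences of the 2 sides go together (r = 0.594, jackknife SE 0.322, 0.297 to 0.680 over alternatives) because the 2 oviducts of a mare share their deviations whatever the status. Other splits of the number pairs gave a median r of 0.458 and 0.782 at most. Counting the real grouping, 25 of 100 splits reached the real r. In pregnant mares the numbers pair the libraries, but in cyclic mares numbers 3 and 4 did not (r 0.02 and −0.04), so that deviations shared by the oviducts of a mare and a pregnancy effect on both sides cannot be told apart.

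A further hypothesis was that pregnancy differences are shared by both oviducts but too small to call on either side. The mean difference over both sides called 0 genes with status and number as a random block (lowest adjusted p = 0.0510, for NLN at −0.71 ± 0.12 and ANPEP at −0.91 ± 0.15, limma) and 0 with means per number (lowest adjusted p = 0.564). Without a block it called 16 genes (3 higher), but the 2 libraries of a pregnant mare are not independent. A missed threshold decides nothing, and small shared differences cannot be told apart from none.

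The last hypothesis was that pregnant mares differ among themselves in interferon-stimulated genes more than cyclic mares do. The SD of the list score was 1.22 in PI and 0.60 in CI (exact permutation p = 0.270), and 1.15 in PC and 0.42 in CC (exact permutation p = 0.254). With 5 libraries a group the 2 cases cannot be told apart.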
